A study of Mus musculus with 6 samples.

How the data were processed

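Total RNA of 6 mammary tumors was extracted with an acid phenol reagent, and sequencing libraries were made with a commercial Illumina RNA kit, per the labels' protocols. Reads were processed with HISAT2 2.0.5, a spliced aligner, and featureCounts 1.5.0-p3, which assigns reads to genes, per the submitters' processing notes. The deposited table gives FPKM, fragments scaled to gene length and library size, for 55243 genes in each library, per the file headers. The formula behind the FPKM values, the use of read strand and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap, antisense genes, and genes with near-identical copies are therefore uncertain. The submitters' processing notes list the build mm9, but 98.7% of the 54809 gene identifiers found in GENCODE M21 have the same start and end there as in the table, so coordinates are given as GRCm38. The table also holds 405 gene models without an Ensembl identifier.

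Each FPKM value multiplied by the gene length in the table and divided by 1 constant per library gave a whole number of reads within 0.01 for 100.0% of values. These recovered reads gave the depth of each library, the 95% exact Poisson intervals of single values, and a count-based alternative. The library size behind the FPKM values was 0.969 to 1.03 times the recovered reads and followed median-of-ratios size factors within −0.31 to 0.29%, so the deposited FPKM values already carry a scaling of that kind. Libraries of 18179278 to 24817729 reads put 1 read in a gene of 1 kb at 0.0392 to 0.0536 FPKM. Library pairs within a group differed by far more than sampling noise, with a chi-square per gene from 57.4 to 91.7, so no pair looked like 1 library deposited in duplicate. This does not show that the libraries came from separate animals. Across genes, which are not independent replicates, Spearman correlations averaged 0.935 between libraries of one group and 0.929 between groups. The first principal component held 39.4% of the variance and did not separate the groups.

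Libraries were grouped by the genotype in their labels, 3 control and 3 cKO. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with a mean FPKM of at least 0.5 over the 6 libraries entered the test, and Msi1, Msi2, Timp3 and Mmp9 were kept at any level, which gave 15982 genes. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Single genes of the series title were also given an exact two-sided permutation test, which cannot go below 0.1 with 3 against 3 libraries.

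The text names Msi1, Msi2, Timp3, Mmp9 and the other Timp genes. In each direction it also names the 10 genes with the smallest p among those with an absolute log2 fold change of at least 1, groups that do not overlap, and a symbol that is not a predicted-gene, clone or RIKEN name. The rule put genes past the adjusted threshold first, and no gene with such a symbol passed. Finally it names 2 to 4 members with the smallest p in each list described. Before the data were examined, 33 gene lists were fixed for pathways, mammary cell types and other cell types that a tumor could hold. The 32 lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, which ranks a list's genes against all others. A correlation estimated for each list and fry, which tests whether a list's genes move one way on balance, were alternatives.

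The fit was tested on simulated reads for 15940 genes drawn with the means and library sizes of these libraries. With each gene's dispersion taken from its spread within groups, it called 37.3%, 71.2% and 80.3% of genes changed 2-, 4- and 8-fold, with 6 false calls. With a dispersion of 0.02 for every gene, where 16015 genes were tested, it called 79.1%, 98.5% and 97%, with 11 false calls. Changed genes were drawn only from those with a mean FPKM of at least 1. These rates therefore do not cover lower genes such as Msi1 and Mmp9. In the first simulation a list of 15 genes raised 4-fold was found with 0 of 32 other lists called. Genes were drawn independently of each other there, so this does not show how often lists of correlated genes are called falsely. Alternatives fixed before the data were examined were other pseudocounts (0.1 and 5), no filter and a minimum mean FPKM of 5, median-of-ratios, quantile and TPM scaling, eBayes without a trend, array weights, a replicate block, protein-coding genes alone, and leaving out each library. The replicate block fits a term for each library number. Control 3 and cKO 1, each alone in its number, then add nothing to the group difference. That difference rests on control 2 and 4 against cKO 2 and 4. Added after seeing the data were limma-voom on the recovered reads, the skeletal muscle list as a covariate, and a fit without control 2 and 3. All 10 splits of the libraries into 3 and 3 were refitted. Similarity between transcripts was measured with blastn 2.17.0 on GENCODE M21 transcripts, and other steps used pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No library and no column of the table was left out.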

Results

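RNA was sequenced from mammary tumors of female mice at 16 weeks of age, with 3 tumors from control mice and 3 from mice with a conditional knockout (cKO) of Msi1. Msi1 encodes Musashi-1, an RNA-binding protein that controls the translation and stability of target messenger RNAs. The libraries carried the numbers 2, 3 and 4 in the control group and 1, 2 and 4 in the cKO group. Reads in the table, recovered from the deposited FPKM values, came to 23444534, 24817729 and 18179278 in control 2, 3 and 4. They came to 21076827, 20177712 and 20925754 in cKO 1, 2 and 4. Between 24125 and 25259 genes had a value above 0. The labels number the libraries but do not say that each came from a separate animal, so p-values measure only the spread between these libraries. Genome coordinates are on GRCm38.

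The series title names Msi1, the metalloproteinase inhibitor Timp3 and the gelatinase Mmp9, and the comparison asks how the tumors' RNA differed when Msi1 was deleted. Msi1 RNA was scarce in both groups, at 0.146 ± 0.110 FPKM (mean ± SD, n = 3) in control tumors and 0.0416 ± 0.0287 FPKM in cKO tumors, a ratio of 0.285. Timp3, which inhibits matrix metalloproteinases in the extracellular matrix, stood at 11.6 ± 4.78 FPKM in control tumors and 13.6 ± 2.17 FPKM in cKO tumors. Mmp9 stood at 0.80 ± 0.541 FPKM in control tumors and 0.747 ± 0.623 FPKM in cKO tumors. The differences of Timp3 and Mmp9 were smaller than the spread between libraries of one group.

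Msi1 (ENSMUSG00000054256) lies on chromosome 5, plus strand, from 115429599 to 115455698. It measured 0.0649, 0.271 and 0.102 FPKM in control 2, 3 and 4, and 0.0582, 0.0581 and 0.00850 FPKM in cKO 1, 2 and 4. These values rest on 60 reads in the control group and 15 in the cKO group. Control 3 held 40 of the 60 control reads, and without it the ratio of cKO to control was 0.499 and the log2 fold change −0.06. Control 2 held 9 reads, with a 95% exact Poisson interval from 4.12 to 17.1, and cKO 1 held 7 reads, with an interval from 2.81 to 14.4, so these libraries could not be separated at this depth. All 3 cKO values lay below all 3 control values, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. In limma the log2 fold change was −0.13 (adjusted p = 0.909), on the log2(FPKM + 1) scale, which understates the change of genes this low. At control values this low, even a complete loss of Msi1 would move that scale little against its SE of 0.164. This limma fit therefore decides nothing about the knockout. The deleted exons are not given in the sources used here, and the value covers the whole gene. Intervals cover counting error only.

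Timp3 (ENSMUSG00000020044, chromosome 10, 86300372 to 86349506, plus strand) had a log2 fold change of 0.29 (SE 0.32, limma adjusted p = 0.904), with a 95% interval from −0.49 to 1.07. Its exact permutation p was 0.6. Control 2 held the lowest Timp3 value, 6.15 FPKM, and without that library the log2 fold change was −0.08. Mmp9 (ENSMUSG00000017737, chromosome 2, 164940780 to 164955850, plus strand) had a log2 fold change of −0.06 (SE 0.33, limma adjusted p = 0.981), with a 95% interval from −0.85 to 0.73. Its exact permutation p was 0.9. Within each group 1 library stood highest, at 1.39 FPKM in control 3 and 1.46 FPKM in cKO 1, and the log2 fold change was 0.17 without control 3 and −0.33 without cKO 1. Msi2, the paralog of Msi1, was at 10.6 ± 1.75 and 10.4 ± 0.326 FPKM in control and cKO tumors. The other inhibitors were Timp1 at 34.6 ± 8.56 and 26.5 ± 6.50 FPKM, Timp2 at 84.3 ± 27.9 and 77.2 ± 17.0 FPKM, and Timp4 at 0.0433 and 0.0817 FPKM, from 16 and 30 reads. The list of tissue inhibitors of metalloproteinases, with 3 tested members, did not pass (camera adjusted p = 0.707).

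**Figure D1:**
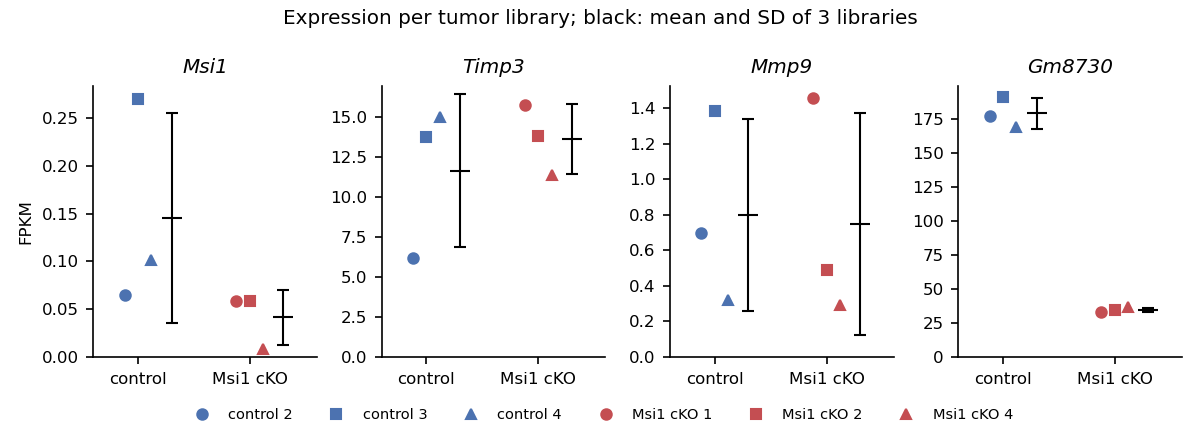
FPKM of Msi1, Timp3, Mmp9 and Gm8730 in each tumor library, with control libraries in blue and cKO libraries in red, and the mean ± SD of each group (n = 3) in black. Gm8730 is the 1 gene past the adjusted threshold, and its cKO values lie from 33.4 to 36.4 FPKM against 168.7 to 191.3 FPKM in the controls.

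Across the genome, 1 of 15982 tested genes passed the adjusted threshold of 0.05. Gm8730 (ENSMUSG00000063696), a processed pseudogene on the minus strand of chromosome 8 from 102864845 to 102865798, fell from 179 ± 11.4 FPKM in control tumors to 34.8 ± 1.5 FPKM in cKO tumors (n = 3 each). Its log2 fold change was −2.33 (SE 0.10, limma adjusted p = 0.0033), and it was lower in 3 of 3 cKO libraries. Gm8730 is 98.7% identical to the messenger RNA of the ribosomal protein gene Rplp0 over 954 of its 954 bases, so its reads are hard to place and its value is uncertain. Its predicted-gene name falls outside the rule for named genes, and it was named after its values were seen. By limma 0 genes were higher past the threshold, with 364 genes higher and 395 lower at an unadjusted p under 0.05, where chance gives 799 in both directions together. The 3 libraries of one group all lay above the 3 of the other for 1658 genes, or 10.4%, where chance gives 10%. Without control 2 or without cKO 2 no gene passed, with an adjusted p for Gm8730 of 0.0571 and 0.0627. Without cKO 4, 39 genes passed, 38 of them higher in the remaining cKO libraries and all 38 immunoglobulin genes or Jchain, the joining chain of secreted immunoglobulins.

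The genes with the smallest p among those at least 2-fold lower on the log2 scale did not pass the adjusted threshold, and their limma adjusted p ranged from 0.366 to 0.883. The AP-1 transcription factor genes Fosb and Fos stood at 6.41 ± 1.08 and 101 ± 25.3 FPKM in control tumors and at 1.16 ± 0.417 and 27.4 ± 5.25 FPKM in cKO tumors (n = 3 each). Col12a1, a collagen that binds the surface of collagen fibrils, stood at 14.9 ± 1.97 and 4.95 ± 1.11 FPKM. Pla2g4a, the phospholipase that releases arachidonic acid, stood at 10.1 ± 1.44 and 4.30 ± 1.52 FPKM. Ptgs2, the inducible cyclooxygenase that turns arachidonic acid into prostaglandin precursors, stood at 2.77 ± 0.339 and 0.807 ± 0.545 FPKM. The secreted ligand gene Wnt7b stood at 7.72 ± 2.02 and 3.26 ± 0.902 FPKM, and the phosphoinositide phosphatase gene Mtmr7 at 11.5 ± 2.95 and 3.60 ± 1.26 FPKM. The microRNA genes Mir7669, Mir1258 and Mir6942 also met the rule, from only 12, 14 and 11 control reads against 1, 2 and 1 cKO reads.

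The genes named on the higher side did not pass either (limma adjusted p = 0.883 for all 10). Gjb2, a gap junction channel protein, stood at 16.0 ± 4.68 FPKM in control and 61.8 ± 35.1 FPKM in cKO tumors (n = 3 each). Dusp4, a phosphatase of MAP kinases, stood at 8.45 ± 3.29 and 21.3 ± 7.16 FPKM. Tnfrsf19, a member of the TNF receptor family, stood at 6.60 ± 3.54 and 17.4 ± 4.27 FPKM, and the tetraspanin gene Tspan1 at 4.25 ± 2.16 and 11.2 ± 2.21 FPKM. Utf1, a chromatin-bound factor of undifferentiated embryonic cells, stood at 1.25 ± 0.366 and 3.77 ± 1.34 FPKM. The kallikrein gene Klk1b11 stood at 0.368 ± 0.207 and 2.27 ± 1.02 FPKM and has close paralogs, so reads could be split among them. The lens crystallin gene Cryba4 stood at 0.420 ± 0.338 and 2.29 ± 1.05 FPKM. The immunoglobulin variable genes Ighv4-1 and Ighv1-58 had 2 and 0 reads in the control group and 34 and 85 in the cKO group, and Mir6941 had 1 and 7 reads.

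**Figure D2:**
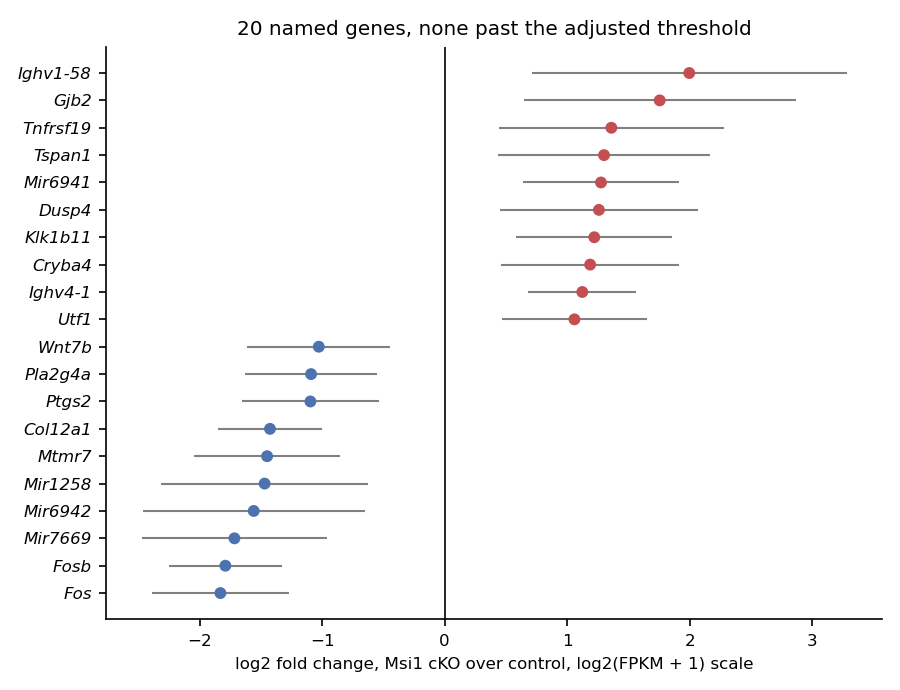
Log2 fold change of cKO over control tumors on the log2(FPKM + 1) scale for the 20 genes named by the rule, as points with 95% limma intervals, with 3 libraries per group. The points run from −1.83 for Fos to 1.997 for Ighv1-58, and none of these genes passed the adjusted threshold.

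Immediate early and stress genes, which cells switch on within minutes of a stimulus, were lower in cKO tumors as a list with the preset correlation. The call was lost when the correlation was estimated (adjusted p = 0.674 with an estimated correlation). Of 16 tested members, 14 lay below 0, 7 had an unadjusted p under 0.05, and 7 had all 3 cKO values below all 3 control values, where chance gives 10% in both directions together. Fosb and Fos passed when adjusted over the list alone, which made 2 genes, against 0 when adjusted over all genes. Dusp1, a phosphatase of stress kinases, stood at 25.5 ± 7.25 and 14.3 ± 1.03 FPKM, and Junb, a partner of Fos proteins, at 63.1 ± 7.17 and 43.7 ± 8.18 FPKM (n = 3 each). The mean log2 level of the list was 4.96, 4.66 and 4.59 in control 2, 3 and 4, and 4.24, 3.93 and 4.31 in cKO 1, 2 and 4. The list passed the camera test with its preset correlation at an adjusted p of 2.05e-07. It did not pass with the correlation of 0.28 estimated from its members (adjusted p = 0.674 with an estimated correlation). The unadjusted p was 0.0518 there and 0.0251 by fry, which the list did not pass either (fry adjusted p = 0.721).

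Lists of the immune response were higher in cKO tumors with the preset correlation, and all 4 lists lost the call when it was estimated (adjusted p = 0.674 with an estimated correlation for each). All 15 members of the antigen presentation list lay above 0, with the peptide transporter gene Tap2 at 15.6 ± 4.17 and 27.4 ± 7.63 FPKM and the immunoproteasome genes Psmb8 at 42.2 ± 17.8 and 84.8 ± 27.9 FPKM and Psmb9 at 12.9 ± 7.14 and 28.7 ± 12.3 FPKM (n = 3 each). All 21 interferon response genes lay above 0, with the antiviral genes Oas2 at 15.8 ± 16.3 and 43.2 ± 31.9 FPKM, Mx2 at 5.36 ± 3.77 and 9.65 ± 3.19 FPKM, and Rtp4 at 67.3 ± 46.1 and 97.1 ± 19.8 FPKM. The T and NK cell list had 11 of 12 members above 0, among them the granzyme gene Gzmb at 2.12 ± 1.92 and 6.65 ± 3.27 FPKM, the T cell co-receptor gene Cd8b1 at 0.784 ± 0.609 and 2.31 ± 1.62 FPKM, and Nkg7, a gene of cytotoxic granules, at 1.93 ± 1.99 and 5.51 ± 4.12 FPKM. All 8 tested B and plasma cell genes lay above 0, among them the B cell receptor genes Cd79a at 0.225 ± 0.0675 and 1.82 ± 1.44 FPKM and Cd79b at 0.378 ± 0.284 and 1.85 ± 1.51 FPKM, and the plasma cell gene Mzb1 at 1.32 ± 0.862 and 7.28 ± 5.79 FPKM. The immunoglobulin light chain gene Igkc, named after its values were seen, stood at 2651 and 1251 FPKM in cKO 1 and 2 and at 18.7 FPKM in cKO 4, against 23.5 to 84.2 FPKM in the controls.

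With the preset correlation the camera adjusted p was 2.13e-05 for antigen presentation, 5.82e-05 for interferon response, 3.43e-04 for B and plasma cells and 0.0101 for T and NK cells. Against these values stood an adjusted p = 0.674 with an estimated correlation for all 4. When adjusted over the list alone, 0 members of these 4 lists passed, as when adjusted over all genes; 3 antigen presentation genes and 1 T and NK cell gene had an unadjusted p under 0.05 in limma. The mean log2 level of interferon response genes was 2.89, 3.76 and 5.43 in control 2, 3 and 4, and 5.76, 4.62 and 4.38 in cKO 1, 2 and 4. Control 4 lay above cKO 2 and 4 in that list, and control 2 and 3, the libraries high in skeletal muscle genes (mean log2 level 4.34 and 3.87), held the low values. Without both, a setting added after seeing the data that leaves 1 control library, interferon response genes passed in the other direction (mean log2 fold change −0.51, camera adjusted p = 0.00647). Antigen presentation and T and NK cell genes then turned without passing (−0.15 and −0.06). Without control 2 alone the interferon call was lost (0.33 against 0.90), with 1.599 without control 4 and 0.48 without cKO 1. With the muscle list as a covariate, also added after seeing the data, the interferon and T and NK cell calls were lost (0.11 and 0.31), and antigen presentation stood at 0.37. That covariate was highest in control 2 and 3 and so partly stood in for genotype. These losses therefore cannot show that muscle tissue was the cause. The T and NK cell call was lost without control 2, control 3 or cKO 1 (0.45, 0.31 and 0.20 against 0.52), with 0.81 without control 4 and 0.86 without cKO 4. Without control 4 the antigen presentation mean was 1.37 against 0.86, without control 3 or cKO 1 it was 0.51 and 0.52, and without cKO 4 or cKO 1 the B and plasma cell mean was 2.88 and 1.14 against 1.80.

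Skeletal muscle genes were lower in cKO tumors with the preset correlation, and the call was lost when it was estimated (adjusted p = 0.674 with an estimated correlation). Control 2 and 3 held the highest levels. Their mean log2 level was 4.34 and 3.87 in control 2 and 3, 0.38 in control 4, and 1.83, 0.55 and 0.39 in cKO 1, 2 and 4. Of 12 tested members, 11 lay below 0, among them the fast myosin gene Myh1 at 2.22 ± 1.96 and 0.116 ± 0.169 FPKM and the troponin gene Tnni2 at 14.0 ± 11.9 and 0.988 ± 0.930 FPKM (n = 3 each). Mb, the oxygen-binding protein myoglobin, lay the other way at 5.69 ± 0.347 and 7.87 ± 1.88 FPKM. The camera adjusted p was 1.16e-04, against an adjusted p = 0.674 with an estimated correlation. When adjusted over the list alone and over all genes 0 members passed, and 0 had an unadjusted p under 0.05 in limma. The mean log2 fold change of −1.94 was −3.18 without control 4 and −1.20 without control 2.

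Lists of mammary epithelial function, adipocytes and the cell cycle were higher in cKO tumors with the preset correlation. All 4 lists lost the call when it was estimated (adjusted p = 0.674 with an estimated correlation, and 0.728 with an estimated correlation for adipocytes). The hormone-sensing luminal list had 11 of 12 members above 0, among them the growth factor gene Areg at 3.85 ± 1.91 and 9.98 ± 4.99 FPKM, Prom1 at 10.7 ± 1.46 and 14.2 ± 3.45 FPKM and the prolactin receptor gene Prlr at 4.29 ± 1.003 and 6.59 ± 3.15 FPKM (n = 3 each). Its mean log2 level was 2.91 and 2.84 in cKO 1 and 2 but 1.76 in cKO 4, below the 2.04, 1.89 and 2.18 of control 2, 3 and 4. The milk and alveolar list had 14 of 16 members above 0, with the transferrin gene Trf at 190.8 ± 42.9 and 314 ± 129 FPKM, Xdh at 24.3 ± 8.61 and 35.6 ± 8.53 FPKM and the folate receptor gene Folr1 at 22.4 ± 14.4 and 43.2 ± 23.7 FPKM. The adipocyte list had 16 of 19 members above 0, with the lipase gene Pnpla2 at 35.1 ± 8.41 and 49.6 ± 14.4 FPKM, the fatty acid synthase gene Fasn at 32.8 ± 5.29 and 44.4 ± 13.4 FPKM and the desaturase gene Scd1 at 145.8 ± 48.7 and 244 ± 98.7 FPKM. The cell proliferation list had 20 of 25 members above 0 but a mean log2 fold change of only 0.14, with the mitotic genes Ccnb1 at 14.6 ± 2.16 and 19.3 ± 2.17 FPKM and Cdc20 at 34.2 ± 7.40 and 45.4 ± 7.30 FPKM and the replication gene Mcm6 at 21.5 ± 1.78 and 29.4 ± 5.94 FPKM.

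The camera adjusted p of these lists was 0.00692 for hormone-sensing luminal cells, 0.0469 for milk and alveolar genes, 0.0412 for adipocytes and 0.0101 for cell proliferation. The adjusted p with an estimated correlation was 0.674, and 0.728 for adipocytes. When adjusted over the list alone, 0 members passed in each, as over all genes, with 1 luminal and 2 proliferation genes at an unadjusted p under 0.05 in limma. In all, 10 of 32 tested lists passed with the preset correlation, 8 higher and 2 lower, and 0 passed with an estimated correlation or by fry, with 0 lists at an unadjusted p under 0.05 with an estimated correlation. Of the 10 splits of the libraries into 3 and 3, 7 gave at least 10 lists, the real split included. The number of lists therefore does not single out genotype. The luminal call was lost without cKO 1 or cKO 2 (mean log2 fold change 0.26 and 0.30), and without cKO 4 the mean was 0.84 against 0.47. Without both control 2 and 3 the luminal and adipocyte calls were also lost (0.32 and 0.12). The proliferation call was lost without control 4 or cKO 2 (0.04 and 0.06), with 0.24 without cKO 4, 0.21 without control 2 and 0.35 without both control 2 and 3 against 0.14. The adipocyte call was lost without control 3, cKO 1 or cKO 2 (0.02, −0.12 and 0.24), with 1.06 without cKO 4 and 0.63 without control 2 against 0.40. The milk and alveolar call was lost without control 3, control 4 or cKO 1 (0.29, 0.30 and −0.04), with 0.80 without cKO 2 and 0.66 without control 2 against 0.42. Both of these calls were also lost with a pseudocount of 0.1, a minimum mean FPKM of 5 or array weights. In these settings the means were 0.469, 0.423 and 0.296 for milk and alveolar genes and 0.418, 0.405 and 0.297 for adipocytes. With the muscle list as a covariate the milk and alveolar mean was 0.83 and the proliferation mean 0.30.

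**Figure D3:**
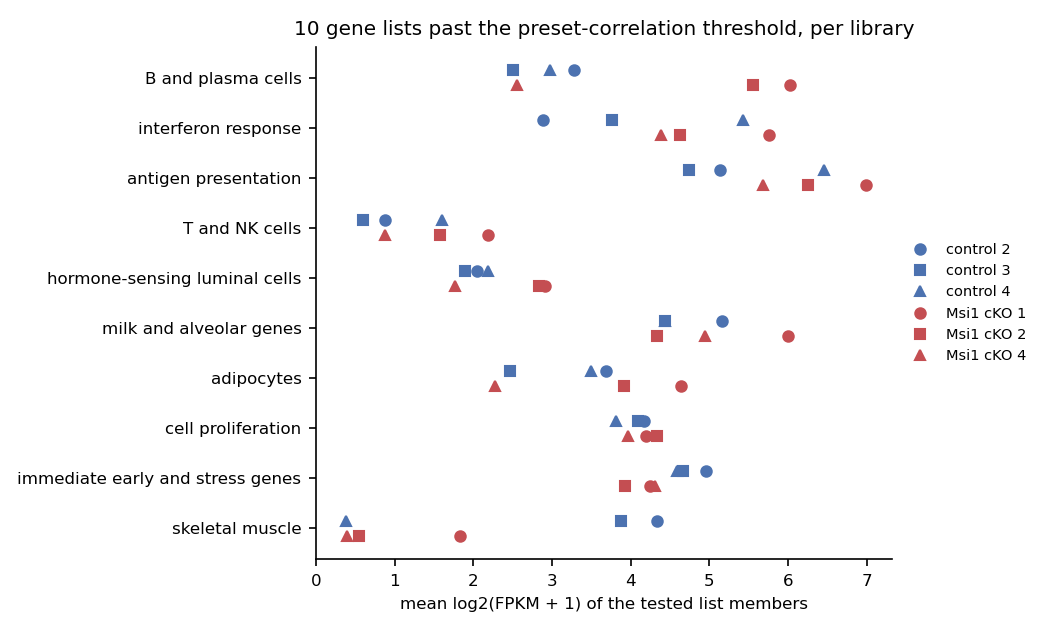
Mean log2(FPKM + 1) of the tested members of the 10 gene lists past the preset-correlation threshold, with 1 point per tumor library, control in blue and cKO in red. In the immediate early list all 3 cKO points lie below all 3 control points, while in the skeletal muscle list control 4 lies at 0.38 beside cKO 4 at 0.39.

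Genes of the extracellular matrix and its breakdown lay on both sides of 0, and the 3 lists below did not pass. Among 13 tested matrix metalloproteinases, 5 lay above and 8 below 0; the collagenase gene Mmp13 stood at 3.66 ± 1.83 and 1.27 ± 0.341 FPKM, Mmp11 at 4.11 ± 0.916 and 2.43 ± 0.223 FPKM and the membrane-bound Mmp15 at 21.7 ± 1.46 and 34.0 ± 9.55 FPKM (n = 3 each). These 3 genes had an unadjusted p under 0.05 in limma; 0 passed when adjusted over the list alone or over all genes, and the list did not pass (camera adjusted p = 0.435). Of 24 extracellular matrix genes, Col12a1 passed when adjusted over the list alone, which made 1 gene against 0 over all genes, and the basement membrane collagen gene Col4a1 stood at 57.9 ± 14.4 and 98.5 ± 30.3 FPKM (list camera adjusted p = 0.214). Among 19 invasion-associated genes, the matrix glycoprotein gene Tnc stood at 12.1 ± 3.91 and 5.31 ± 3.01 FPKM and the cathepsin gene Ctsl at 44.7 ± 6.60 and 31.8 ± 7.21 FPKM (list camera adjusted p = 0.149).

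Lists of signaling and cell identity did not pass. Of 10 tested Musashi family members and reported Musashi targets, 9 lay below 0; the TGF-beta mediator Smad3 stood at 11.6 ± 0.223 and 14.9 ± 0.963 FPKM and the Notch ligand gene Jag1 at 5.63 ± 1.40 and 3.53 ± 0.830 FPKM (n = 3 each; list camera adjusted p = 0.233). In the Notch pathway list, 14 of 20 genes lay below 0, with Notch4 at 2.31 ± 0.838 and 1.48 ± 0.0796 FPKM (camera adjusted p = 0.244). All 9 tested Wnt pathway targets lay above 0 (camera adjusted p = 0.0515). The epithelial identity list had Grhl2 at 9.997 ± 0.845 and 8.03 ± 0.793 FPKM and the tight junction gene Cldn4 at 61.5 ± 27.4 and 86.3 ± 28.5 FPKM (camera adjusted p = 0.549). The mesenchymal identity list had the cadherin gene Cdh11 at 3.20 ± 0.576 and 1.70 ± 0.662 FPKM and Twist1 at 2.91 ± 1.495 and 4.62 ± 1.86 FPKM (camera adjusted p = 0.748). Among basal and myoepithelial genes, the contractile genes Cnn1 and Myh11 stood at 6.52 ± 5.72 and 4.36 ± 3.94 FPKM in control and at 21.9 ± 9.50 and 15.8 ± 9.83 FPKM in cKO tumors (camera adjusted p = 0.0986). Among stem cell-associated genes, the retinal dehydrogenase gene Aldh1a3 stood at 7.64 ± 2.50 and 4.01 ± 0.788 FPKM and Sox9 at 36.1 ± 9.27 and 26.2 ± 3.81 FPKM (camera adjusted p = 0.233). When adjusted over the list alone, 0 genes of these lists passed, as over all genes.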

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

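The limma-voom fit, the skeletal muscle covariate and the fit without control 2 and 3 were chosen after seeing the data. Gm8730 stayed lower in every setting that tested it, with log2 fold changes from −2.44 to −2.21, and it passed in all but the replicate block, the fits without control 2 or cKO 2, the muscle covariate and the fit without control 2 and 3. The count of genes past the threshold was 0 rather than 1, and the count lower 0, with the replicate block, with protein-coding genes alone (which leave Gm8730 out), with the muscle covariate (adjusted p of Gm8730 = 0.105) and without control 2 and 3 (0.136; the lone control library is assumed to vary like the cKO libraries). Leaving out single libraries moved the count from 0 to 39, the count higher from 0 to 38 and the count lower from 0 to 1, and limma-voom called 1 gene. At an unadjusted p under 0.05 the count was 400 with the replicate block, 531 with protein-coding genes alone, 656 with the muscle covariate and 659 without control 2 and 3. Numbers 2 and 4 are shared by both groups, but same-numbered libraries did not deviate together (correlations −0.04 and −0.17). The replicate block rests on numbers 2 and 4, so its results decide nothing, whether calls were kept or lost or signs changed (Gm8730 −2.25). Msi1 stayed lower, from −0.18 to −0.06 without single libraries, −0.73 with a pseudocount of 0.1 and −1.85 with limma-voom. It passed in no setting, and the log2(FPKM + 1) scale leaves a loss of this gene little room. Mmp9 turned to 0.016 with array weights, 0.34 with the muscle covariate and 0.35 without control 2 and 3, and ranged from −0.33 to 0.17 without single libraries. Timp3 turned to −0.14 without control 2 and 3 and ranged from −0.08 to 0.50 without single libraries. Among other genes, the Msi2 log2 fold change turned to 0.024 with array weights, 0.081 with the replicate block and ranged from −0.143 to 0.077 without single libraries; the Timp2 log2 fold change ranged from −0.349 to 0.138; Folr1 (−0.003) and Prlr (−0.017) turned with the replicate block. The number of gene lists past the preset threshold ranged from 8 to 15 over the settings and was 0 with an estimated correlation and by fry; the immediate early list passed with the preset correlation in each of these settings, with an adjusted p from 3.39e-09 to 4.26e-04. The mean log2 fold change of members turned with the replicate block in T and NK cells (−0.01), adipocytes (−0.49, past the threshold in the other direction, adjusted p = 0.0201) and milk and alveolar genes (−0.16). Without control 2 and 3 it turned in T and NK cells (−0.056), antigen presentation (−0.15), interferon response (−0.51, past the threshold in the other direction, adjusted p = 0.00647) and skeletal muscle (0.54, 0.0403), the last fixed by removing the libraries high in it. Without single libraries it ranged from −0.12 to 1.06 in adipocytes and from −0.037 to 0.799 in milk and alveolar genes. The milk and alveolar call was lost with a pseudocount of 0.1 (adjusted p = 0.0579), a minimum mean FPKM of 5 (0.146), median-of-ratios scaling (0.0534), array weights (0.121) and protein-coding genes alone (0.0507). The adipocyte call was lost with a pseudocount of 0.1 (0.0764), no filter (0.054), a minimum mean FPKM of 5 (0.146) and array weights (0.108). With the replicate block the luminal, interferon and antigen presentation calls were lost (camera adjusted p = 0.391, 0.145 and 0.427). With the muscle covariate, which overlaps with genotype, the interferon and T and NK cell calls were lost (camera adjusted p = 0.642 and 0.22). The muscle call was lost there too (0.90), which was fixed by using that list as its own covariate. Of 219 values of the 10 called lists under alternatives, 161 kept the call, 49 lost it and 9 turned, the fixed muscle values included. Apart from these constructions the cause was not tested. Depth limits Msi1, at 1 to 40 reads per library, and more so Timp4, the microRNA genes and Ighv4-1, which hold fewer reads.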

Other observations

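Cell types other than tumor epithelium showed no list past the preset threshold beyond the immune cells, muscle and adipocytes above. All 10 Schwann cell and nerve genes lay above 0 (camera adjusted p = 0.0746), as did all 8 tested genes of dendritic and mast cells (0.0986) and 12 of 13 mitochondrial transcripts (0.0799). Macrophage genes lay on both sides, 10 above and 6 below 0 (camera adjusted p = 0.748), as did neutrophil genes, 5 above and 4 below (0.707), fibroblast genes, 6 above and 10 below (0.563), and endothelial and pericyte genes, 11 above and 7 below (0.825), whose mean was −0.03 and median 0.02. Ribosomal protein genes, 19 of 24 above 0, had a camera adjusted p of 0.115. Hypoxia and glycolysis genes, 15 of 20 above 0, had 0.295, and skin genes, 4 of 5 above 0, had 0.274. Erythroid genes had 0.682, and the alpha globin gene Hba-a2, named after its values were seen, passed when adjusted over the list alone, at 1.24 ± 0.283 FPKM in control and 0.217 ± 0.191 FPKM in cKO tumors (n = 3 each), against 0 genes over all genes. Hba-a2 has a near-identical neighbor, Hba-a1, so its value is uncertain. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in all 6 libraries, which are labelled female.

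The tests of skeletal muscle tissue, the count of list splits, and the reading of Gapdh, Rps2 and Rps18 one by one were chosen after the results were seen. For those 3 genes a limit of 2-fold had been set beforehand for the genes together, and the same limit was kept for each.

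Gm8730 fell in all 3 cKO libraries, and its reads may be shared with Rplp0, since the transcripts are 98.7% identical with 12 mismatches. Rplp0 was not alone: 3 genes, Rplp0 among them, were at least 95% identical over at least 80% of Gm8730. The shares that follow cover Gm8730 and Rplp0 only. Gm8730 took 7.88 ± 0.40% of the reads of both genes in control and 1.43 ± 0.13% in cKO tumors, while Rplp0 stood at 1207 ± 111 and 1385 ± 155 FPKM. Rplp0 lies 103.8 kb from Msi1, so a variant in a chromosome segment that travelled with the engineered allele is a candidate explanation. Genes within 10 Mb of Msi1 held more unadjusted p under 0.05, 19 of 272 or 7.0% against 4.7% elsewhere, with an odds ratio of 1.52 and a one-sided Fisher's exact p of 0.0603, which leaves it open. A change of Gm8730 itself with the loss of Msi1 was not tested and stays open, and only the reads would show which bases they carry.

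For the count of genes, 10 splits of the libraries into 3 and 3 are too few for a share under 0.05. The real split gave 1 gene and the highest other 11, 3 of the 10 splits gave as many, and the split with 11 sets control 2, control 3 and cKO 4 apart, which points to a structure of the samples other than genotype. For lists the real split gave 10 and the highest other 16, with 7 of the 10 splits, the real one included, giving at least as many. The number of called lists therefore does not set the genotype grouping apart from other groupings.

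The skeletal muscle list was highest in control 2 and 3, with an intermediate level in cKO 1, and muscle tissue in those libraries may account for it. Of 12 tested members, 11 were higher in both libraries than in each of the other 4, and the actin gene Acta1, abundant in muscle and named after its values were seen, stood at 119 and 79.5 FPKM there, 0.210 FPKM in control 4 and 8.60, 0.846 and 0.0963 FPKM in the cKO libraries. The exception was Mb, which these tumors expressed in both groups. Control 4 minus cKO 1, 2 and 4 was −1.45, −0.17 and −0.01 in mean log2 level, so control 4 lay above no cKO library. Low levels of these genes thus also occurred in a control. A loss of these genes with Msi1 stays open, since 1 control library cannot decide. The first bound against such a loss, control 4 below the highest cKO library, was met. It was replaced by a stricter bound after the result was seen.

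Gapdh, Rps2 and Rps18, named after their values were seen, differed 10.2-, 23.8- and 14.1-fold between libraries of one group, although cells express them steadily. For Rps2, reads may have moved between the gene and its annotated near-identical copies, since the gene and 25 copies together differed only 1.47-fold among the cKO libraries. For Rps18 the gene and 5 copies together differed 2.05-fold among the controls, just over the limit, so such a move cannot be told apart from other causes. For Gapdh the gene and 72 copies together still differed 11.49-fold, which argues against a move of counted reads between them. The sum holds only counted reads, and the treatment of reads that map to several places is not given. Muscle tissue in control 2 and 3 stays open for Gapdh: 5 other glycolysis genes had a median fold of 1.14 over control 4, but their high levels would hide a gain the size of that of Gapdh (26.0 FPKM, a median fold of 1.16), so the bound set beforehand could not decide. No biological explanation and no strain variant was tested for these 3 genes.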
